A study of Arabidopsis thaliana with 22 samples.

How the data were processed

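Expression was measured in leaf 10 of Arabidopsis thaliana Col-0 on 22 Affymetrix arrays, which carry probe sets of short oligonucleotides. Per the labels, biotin-labelled RNA was made from total RNA with a kit that amplifies from the 3-prime end, and the arrays of a group are biological replicates. The deposited values are log2 expression values, 12570 probe sets by 22 arrays, between -6.80 and 6.54. Each array had a median of 0 over exactly these rows, so the deposited log2 values are centred on the array median, and a value is a level relative to the median probe set of its array. The base of the logarithm was inferred from the range of the values, and folds given here assume base 2. Background correction, summarisation of probes and any earlier selection of probe sets are not given in the sources used here. Centring sets the median probe set of every array to 0, so a change shared by most transcripts is not visible. Scan dates and slides are not given in the sources used here, so no scan batch was tested.

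The 59 control probe sets were left out, and 12511 probe sets were tested. The platform annotation given with the table named exactly 1 gene for 6782 of them and several genes for 262, and left 5467 unnamed here. Names were updated through gene identifiers to the TAIR10.1 gene table, in which 16 of the named probe sets had no match and kept their older name. Genes are named only from probe sets with exactly 1 gene. Where a gene had several, the probe set with the highest mean over the 22 arrays stood for it in the gene lists. The gene tables and the array do not name a shared genome build, so no coordinates are printed.

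The 6 groups of leaf stage and CO2 level were fitted in 1 cell-means model with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes), with 16 residual degrees of freedom and 1 estimate of the spread per probe set for all stages. Contrasts were elevated minus ambient CO2 within each stage, the differences of these effects between stages, a moderated F test of all 3 stages together, and the stages at ambient CO2. P-values were adjusted by the Benjamini-Hochberg method over the 12511 probe sets of a contrast, all tests are two-sided, and a probe set was called at an adjusted p under 0.05. Errors beside log2 changes are the moderated standard errors (SE) of that fit, and errors beside group levels are SDs.

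Before the data were examined, 29 gene lists were written by locus, and the glycolysis, TCA cycle and electron transport lists were joined as respiration genes. At least 5 measured members were required for a test, which 6 lists and the joined list met. Members without a named probe set could not be traced, so these lists were seen in part. Such members may still lie among the tested probe sets that were left unnamed here or carried several genes. A member is called measured here if it had a named probe set. Measured were 64 of 145 respiration genes: 11 of 40 in glycolysis, 16 of 41 in the TCA cycle and 37 of 64 in electron transport. Light reactions had 6 of 43, photorespiration 6 of 20 and cell wall loosening 5 of 19. Of the other lists, 10 had no member on a named probe set, among them every list of markers of xylem, phloem and shoot meristem cells, so those cell types were not analysed here. A list of cytosolic ribosomal proteins was left out because the tables hold no gene descriptions. A further 12 lists were made from gene names in the annotation once the values were at hand but before any comparison was computed, and are reported as additional lists. Lists were tested with limma's camera on the same fit with its preset inter-gene correlation of 0.01, adjusted over the lists fixed first and the contrasts of a family, and apart from these over the additional lists. The estimated correlation of camera and limma's fry were alternatives. The count of called members is given over all probe sets and adjusted over the list alone.

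The rule for named genes was also fixed before the data were examined. For each CO2 comparison it takes the 8 largest rises and 8 largest falls among called probe sets whose elevated arrays all lie on 1 side of all ambient arrays, or, with none called, the 5 rises and 5 falls with the smallest p. It adds up to 4 members of each list with the smallest p per CO2 comparison, the 8 smallest p of the F test, the 5 largest rises and 5 largest falls per stage comparison, and 3 members of each list there. Any list member may be named beside its list's count.

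The scripts were tested on simulated arrays in which 200 of the 12511 probe sets were changed in 1 stage. They had the real ambient means and 1 spread per probe set, the same at every stage. Noise was drawn independently, so structure shared across an array was absent. A further small list of probe sets was shifted to test the list method. Each stage had a single run, so the shares below do not rank primordia against mature leaves. At a simulated 1.5-fold change, 77.6% of the changed probe sets were called in primordia, 56.7% in expanding leaves and 67.2% in mature leaves. At 2-fold the shares were 94.0%, 94.0% and 92.5%. The number of arrays (3 or 4 per group) limits the precision of every value.

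Alternatives fixed beforehand were fits of single stages, quantile normalization over all arrays and within stages, removal of the dimmest 30% or 50% of probe sets, an intensity trend with robust eBayes, array weights, a replicate block, each array left out in turn, 1 probe set per gene, other thresholds, and the stages at elevated CO2. Centring on the median was void, since the values are already centred, and a logarithm with an offset did not apply. Fits without elevated-CO2 mature replicates 3 and 4 together, with the developmental position of an array, and with the 3-prime minus 5-prime signal of control transcripts as a covariate were chosen after seeing the data. Other splits of the same arrays were counted, with at most 100 draws per contrast. Figures were drawn with matplotlib.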

Results

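Transcript levels were compared between ambient (370 ppm) and elevated (750 ppm) CO2 at 3 stages in the life of leaf 10: dissected primordia, leaves in rapid expansion, and fully expanded mature leaves. The series title puts the question as whether the response of leaf dark respiration to elevated CO2 depends on the developmental stage. Primordia and mature leaves had 4 arrays per CO2 level and expanding leaves had 3. Each primordia replicate pooled 20 plants. Plants grew for 7 days at 370 ppm under a 10 h day at 21 °C, a 14 h night at 18 °C and 300 µmol m-2 s-1 of light, and were then randomized between 2 chambers. Per the labels, 2 chambers held the 2 CO2 levels, so CO2 and chamber cannot be told apart at any stage.

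Developmental stage dominated the values. The first principal component held 81.3% of the variance and ran from primordia through expanding to mature leaves, and the second held 7.8%. Replicates of a group correlated over probe sets with r between 0.969 and 0.992. Elevated-CO2 mature replicates 3 and 4 stood apart from the other mature arrays on the second component, at 36.3 and 27.7 against -7.7 to 14.9.

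**Figure D1:**
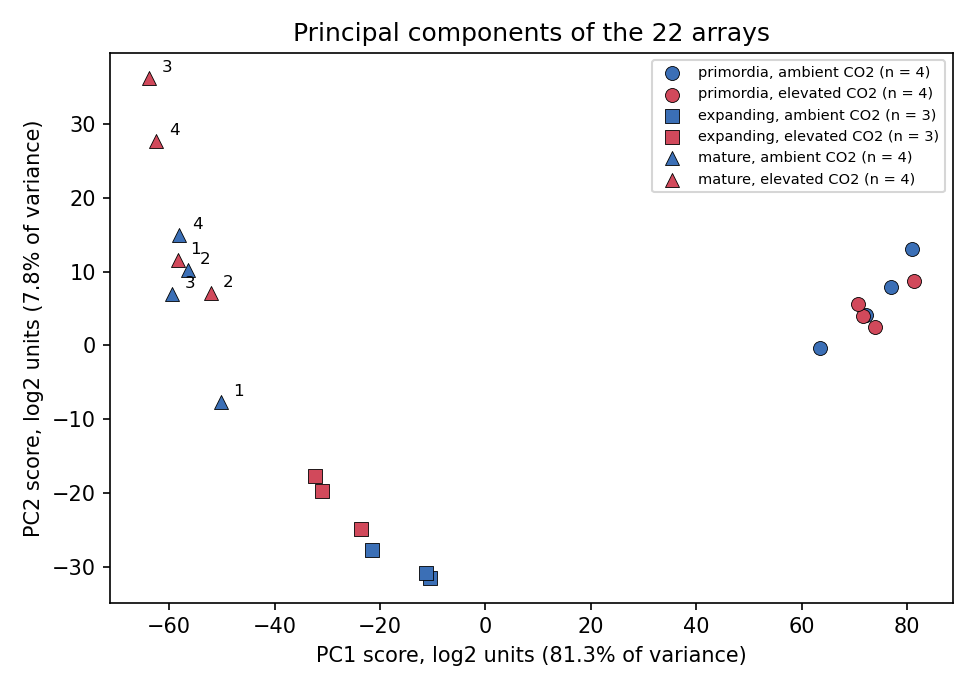
Scores of the 22 arrays on the first (x axis) and second (y axis) principal components, in log2 units; shape marks the stage, colour the CO2 level, and numbers the replicates of mature leaves. Stages separate along the first component, and elevated-CO2 mature replicates 3 and 4 reach 36.3 and 27.7 on the second.

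Between primordia and expanding leaves at ambient CO2, all 6 measured genes of the light reactions rose. SWEET11, a sucrose exporter, was 5.51 ± 0.18 (SE) higher on the log2 scale, AT1G23130 was 5.83 ± 0.28 higher, and BGLU33, a beta-glucosidase, 5.21 ± 0.25 higher. AT5G18600 and AT1G30250 completed the 5 largest rises, at 5.11 ± 0.23 and 5.08 ± 0.39. The largest falls were in GLC (-4.69 ± 0.24), AT4G10270 (-4.47 ± 0.31), AT2G28790 (-4.36 ± 0.28), DI21 (-4.12 ± 0.21) and AT5G55180 (-2.98 ± 0.16). ATSPS4F, a sucrose-phosphate synthase, rose by 4.07 ± 0.30.

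All 6 measured members of the light-reaction list rose between these stages (6 also when adjusted over the list alone; median 1.03), among them LHCB4.1 (1.02 ± 0.09), PSBY (1.29 ± 0.12) and ATPC1 (1.29 ± 0.12). The list's camera adjusted p was 0.00860, and adjusted p = 0.571 with an estimated correlation. Of 6 photorespiration genes, 5 rose and 1 fell (the same counts adjusted over the list alone; camera adjusted p 0.0619); HPR, hydroxypyruvate reductase, rose by 1.43 ± 0.13 and AT1G80380, glycerate kinase, by 1.55 ± 0.13. In the Calvin cycle, PRK (phosphoribulokinase) rose by 1.57 ± 0.12. Both measured cell cycle genes fell, PRL, an MCM helicase subunit of DNA replication, to 0.308 times its level in primordia, and the mitotic kinase AUR1 by a log2 change of -1.82 ± 0.25. The primordium regulators YAB3 (-0.81 ± 0.12) and PHV (-0.83 ± 0.13) fell, while YAB5 rose by 0.72 ± 0.16.

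Respiration genes split evenly at this step: 16 of 64 rose and 16 fell (16 and 15 adjusted over the list alone). Within glycolysis, 4 of 11 rose and 5 fell (4 and 5 adjusted over the list alone). The falls included the subunits of pyrophosphate-dependent phosphofructokinase, AT1G76550 (-1.21 ± 0.10), AT1G20950 (-0.89 ± 0.09) and AT1G12000 (-0.75 ± 0.12). In the TCA cycle list, 7 of 16 rose and 4 fell (7 and 4 adjusted over the list alone), and in electron transport 5 of 37 rose and 7 fell (5 and 6). NDB2, an external NADH dehydrogenase that bypasses complex I, rose by 1.61 ± 0.32. The cell wall loosening list went both ways, with 2 of 5 higher and 3 lower (2 and 3 adjusted over the list alone), EXPA8 at 3.08 ± 0.26 and EXPA15 at -1.04 ± 0.19. In limma, 8292 of 12511 probe sets were called, 4389 higher and 3903 lower in expanding leaves, and 2481 differed at least 2-fold.

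From expanding to mature leaves, BCAT4, a methionine aminotransferase of glucosinolate synthesis, rose by 3.14 ± 0.38 and the metallothionein gene MT1C by 2.52 ± 0.24. AT2G04795 rose by 2.18 ± 0.20, the ATP sulfurylase gene APS4 4.27-fold and AT1G69450 by 2.05 ± 0.20. The largest falls were in AT4G29020 (-4.26 ± 0.33), AT5G48490 (-3.65 ± 0.28), AT1G31690 (-3.23 ± 0.30), AT1G11850 (-3.14 ± 0.27) and Cpn60beta2, a plastid chaperonin (-3.04 ± 0.31). PRL (-1.13 ± 0.14), AUR1 (-1.58 ± 0.25) and STOMAGEN (-1.34 ± 0.36), which promotes stomatal density, also fell.

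Of the 64 respiration genes, 22 fell and 3 rose between expanding and mature leaves (21 and 3 adjusted over the list alone). Glycolysis had 6 lower and 0 higher of 11 (6 and 0 adjusted over the list alone), with AT1G12000 at -1.21 ± 0.12. Electron transport had 12 lower and 2 higher of 37 (12 and 2), with CYTC-1 (cytochrome c) at -0.36 ± 0.06, and the TCA cycle 4 lower and 1 higher of 16 (2 and 0 adjusted over the list alone). The camera adjusted p was 0.0619 for respiration genes and for electron transport, so these lists did not pass as wholes against the other probe sets. Light reactions had 1 of 6 lower (0 adjusted over the list alone), photorespiration 2 of 6 (2) and cell wall loosening 2 of 5 lower and 1 higher (2 and 1), with XTH16 at -2.80 ± 0.30. In all, 5541 probe sets were called, 2464 higher and 3077 lower in mature leaves, and 704 differed at least 2-fold.

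In mature leaves, PDF1.2, a defensin induced by jasmonate and ethylene, was 1.88 ± 0.39 (SE) higher at elevated CO2, at 2.38 ± 0.71 (SD, n = 4) against 0.50 ± 0.66 (SD, n = 4) at ambient CO2. AT3G09440, a heat shock protein 70, rose by 0.95 ± 0.16, and AT3G16530, a legume-type lectin, by 1.00 ± 0.26. The other named rises were AT1G43910 (1.27 ± 0.31), AT5G46230 (1.12 ± 0.28), AT3G22060 (1.05 ± 0.29), AT5G19240 (0.96 ± 0.23) and AT3G19010 (0.88 ± 0.21). The rule takes only genes whose arrays did not overlap between CO2 levels, which left out AT3G27400 (1.37 ± 0.21), called as well. AT1G60590, a pectin lyase-like gene, was lower, at a change of -1.54 ± 0.29, at 0.86 ± 0.87 (SD, n = 4) against 2.39 ± 0.42 (SD, n = 4).

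The other named falls in mature leaves were AT4G24790 (-1.31 ± 0.20), AT4G28780, a GDSL lipase (-1.12 ± 0.24), the methyltransferase-like neighbours AT1G69523 (-1.06 ± 0.23) and AT1G69526 (-0.87 ± 0.19), AT3G23840 (-0.98 ± 0.17), the basic helix-loop-helix gene AT4G01460 (-0.90 ± 0.17) and the protein kinase gene AT1G56720 (-0.89 ± 0.13). Elevated replicates 3 and 4 carried much of several falls: without both, an alternative chosen after seeing the data, AT1G60590 was at -0.88, AT4G28780 at -0.44, AT4G01460 at -0.54, AT1G69523 at -0.69 and AT1G69526 at -0.56, whereas AT4G24790 was at -1.04. In that fit 2 of the 25 named genes called in mature leaves passed, AT3G09440 and AT1G56720, although 18 of the 25 moved by at most 1.5 times, among them PDF1.2 (1.69), AT1G43910 (1.14), AT5G46230 (1.06) and AT3G23840 (-0.95). Of 5 cell wall loosening genes, 1 fell, EXPA8 (-0.89 ± 0.24); adjusted over the list alone, 2 did, and the list's camera adjusted p was 0.541, with a median of its members (0.005) opposite in sign to their mean (-0.21). No photorespiration gene passed over all probe sets and 1 of 6 was lower when adjusted over the list alone, AT1G80380 (-0.36 ± 0.12, adjusted p 0.0882); all 6 had negative changes, with a camera adjusted p of 0.0735. All 6 light-reaction genes had negative changes too and none passed, over all probe sets or over the list alone (camera adjusted p 0.28). Among lists too short to test, NDB2 was at 0.96 ± 0.30 (adjusted p 0.0721), DPE1 of starch degradation at -0.33 ± 0.10 (adjusted p 0.0590) and STOMAGEN at -0.90 ± 0.33 (adjusted p 0.123), none past the threshold.

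**Figure D2:**
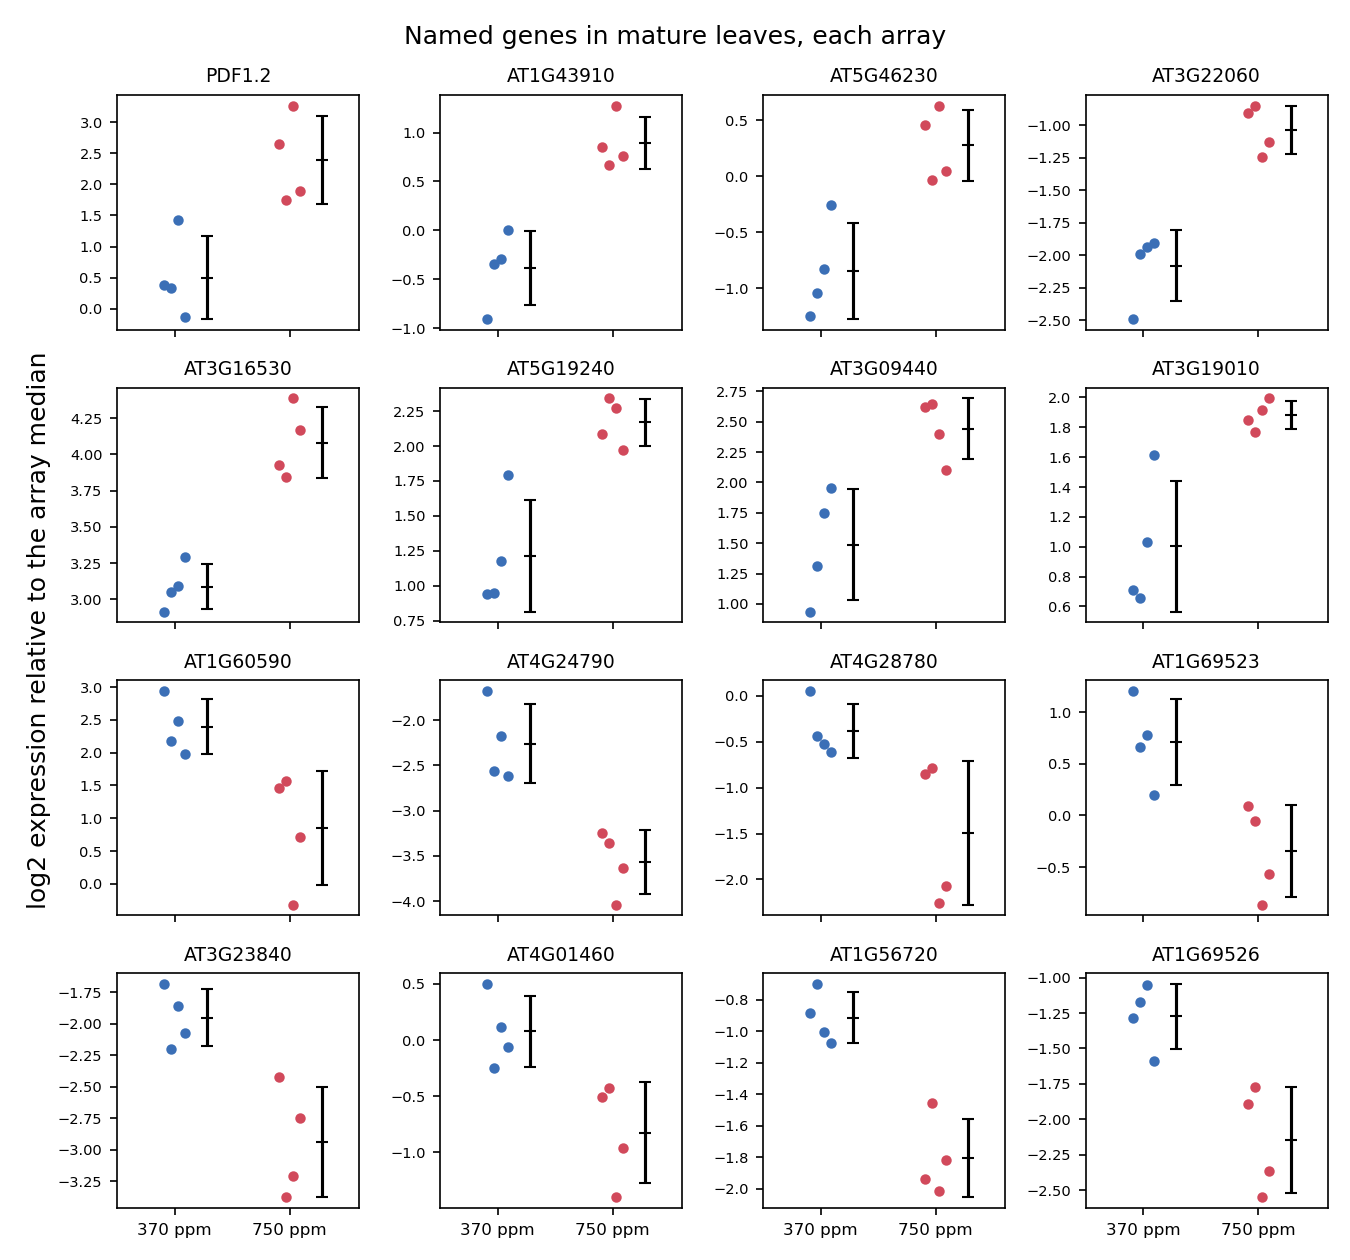
Log2 expression relative to the array median (y axis, a separate scale per panel) of the 16 genes named by rule in mature leaves, each array as a point at 370 or 750 ppm CO2 (n = 4 each), with mean and SD as bars. PDF1.2 averages 2.38 at elevated against 0.50 at ambient CO2, and AT1G60590 0.86 against 2.39.

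In limma, 488 of 12511 probe sets were called in mature leaves, 220 higher and 268 lower, with a median size of 0.54, and 26 differed at least 2-fold; 252 had exactly 1 gene. Fitted on the mature arrays alone, limma called 0, with 2087 at an unadjusted p under 0.05 against 2754 in the joint fit, whose spread is shared with the less variable other stages (median residual SD 0.143 in primordia, 0.158 in expanding and 0.179 in mature leaves). The count was 64, 138, 145 and 849 without ambient replicate 1, 2, 3 or 4 and 1051, 60 and 137 without elevated replicate 2, 3 or 4, and without elevated replicates 3 and 4 together, an alternative chosen after seeing the data, 30.

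In expanding leaves the CO2 effect passed the test for no probe set: limma called 0 of 12511, with 1837 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0711. By the fixed rule, the 5 positive changes with the smallest p among named genes were AT3G08990 (0.90 ± 0.17), the copper amine oxidase CuAO1 (0.74 ± 0.15), AT1G21920 (0.46 ± 0.09), AT3G56820 (0.56 ± 0.12) and AT2G16595 (0.80 ± 0.18). The 5 negative changes were AT1G77550 (-0.62 ± 0.10), AT1G78930 (-0.82 ± 0.15), AT5G19210 (-0.52 ± 0.10), AT1G52930 (-0.67 ± 0.14) and AT5G27330 (-0.91 ± 0.19). Adjusted p-values of these 10 genes were between 0.0711 and 0.105. In glycolysis, 3 of 11 genes were lower when adjusted over the list alone and 0 over all probe sets: AT5G42740, the cytosolic phosphoglucose isomerase (-0.36 ± 0.11), AT1G12000 (-0.38 ± 0.13) and AT1G20950 (-0.27 ± 0.09); the list's camera adjusted p was 0.211. With limma's fry, an alternative that asks whether the list's own genes move and does not compare them with others, glycolysis passed as lower (8 of 11 negative, median -0.11), with an adjusted p of 0.0406 for direction and 0.0229 for change either way. No other tested list fixed beforehand had a member past the threshold in expanding leaves, over all probe sets or over the list alone.

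The count of 0 in expanding leaves moved with the setting. With array weights it was 387, with quantile normalization of all arrays 12, without ambient replicate 1 it was 81, and with the 3-prime minus 5-prime signal of control transcripts as a covariate, chosen after seeing the data, 279.

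In primordia, MT1C was the only probe set called among 12511 in limma: it was 1.63 ± 0.22 higher at elevated CO2 (adjusted p 0.00338), at -0.06 ± 0.41 (SD, n = 4) against -1.68 ± 0.50 (SD, n = 4). At an unadjusted p under 0.05 there were 472 probe sets. MT1C was not called in expanding leaves or in mature leaves, at 0.45 ± 0.25 and 0.34 ± 0.22. No member of a tested list fixed beforehand passed in primordia, over all probe sets or over the list alone. AT5G41670, a 6-phosphogluconate dehydrogenase, was at 0.65 ± 0.15 (adjusted p 0.448) and ATSPS4F at -0.72 ± 0.27. Fitted on the primordia arrays alone the count was 0, with MT1C at an adjusted p of 0.379 (0.000989 to 0.385 over all alternatives for MT1C), and without elevated replicate 2 it was 8.

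Of 16 measured TCA cycle genes, 3 rose at elevated CO2 in mature leaves and 0 fell (3 and 0 adjusted over the list alone), 14 had positive changes and the median was 0.17. The 3 were AT4G26910, the dihydrolipoyl succinyltransferase of 2-oxoglutarate dehydrogenase (0.51 ± 0.12, adjusted p 0.0216), SDH1-1, the flavoprotein of succinate dehydrogenase (0.33 ± 0.09, adjusted p 0.0403), and AT5G08300, a succinyl-CoA ligase subunit (0.27 ± 0.07, adjusted p 0.0427). They catalyse neighbouring steps of the cycle. The TCA cycle list passed camera with an adjusted p of 0.00158, and adjusted p = 0.230 with an estimated correlation.

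Over the 64 measured respiration genes in mature leaves, 45 had positive changes, the same 3 rose and 0 fell (3 and 0 adjusted over the list alone), the median was 0.07, and the camera adjusted p was 0.00532, with adjusted p = 0.730 with an estimated correlation. Electron transport, with 26 of 37 positive and no member called, had a camera adjusted p of 0.0859 and passed fry for change either way (adjusted p 0.0229) but not for direction (0.368); CYTC-1 and CYTC-2, the genes of cytochrome c, were at 0.16 ± 0.06 and 0.26 ± 0.11. Glycolysis had 5 of 11 positive and no member called (camera adjusted p 0.799), with AT5G63680, a pyruvate kinase, at 0.48 ± 0.15. In expanding leaves, 24 of 64 respiration genes were positive (median -0.04, camera adjusted p 0.490) and in primordia 37 of 64 (median 0.02, camera adjusted p 0.597), and no member was called at either stage. Without elevated replicate 1 of mature leaves, the camera adjusted p of the 64 genes was 0.0595. Over all alternatives the adjusted p ran from 0.000123, with fry for change either way, to 0.730, with camera's estimated correlation.

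**Figure D3:**
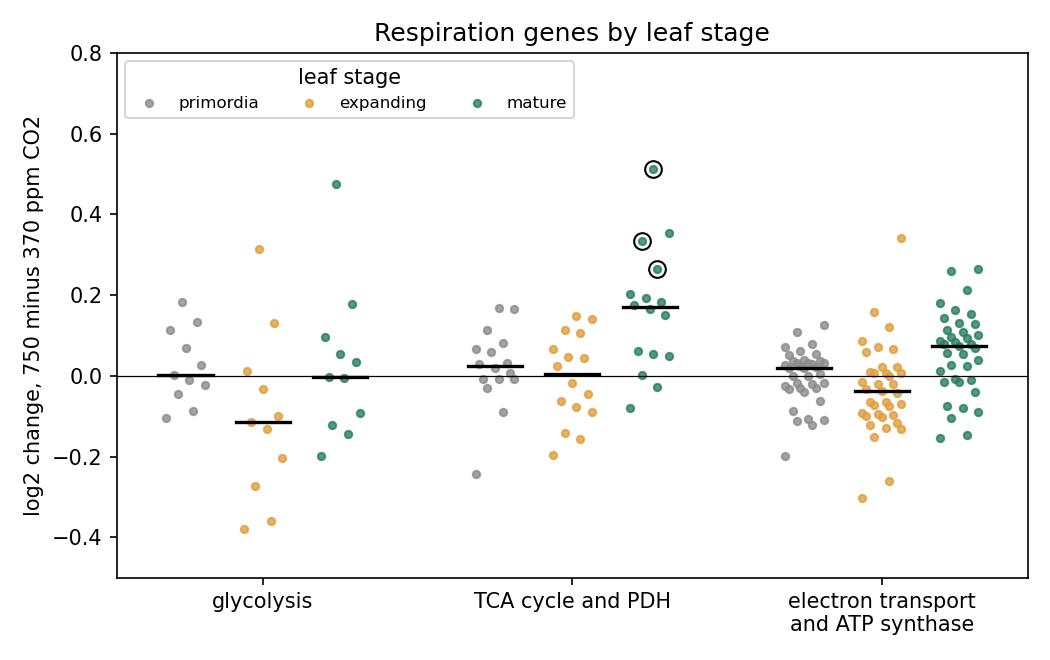
Log2 change at 750 against 370 ppm CO2 (y axis) of each measured gene of glycolysis (11), the TCA cycle with pyruvate dehydrogenase (16) and electron transport with ATP synthase (37); colour marks the stage, bars the median, and rings the genes past an adjusted p of 0.05. The TCA cycle genes of mature leaves lie highest, with a median of 0.17 and 3 ringed genes.

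The CO2 effect itself differed between stages for 4 probe sets by the F test of all 3 stages (1724 at an unadjusted p under 0.05). AT1G77550 was at 0.18 ± 0.09 in primordia, -0.62 ± 0.10 in expanding and 0.35 ± 0.09 in mature leaves (adjusted p 0.0103). AT4G36640 was at -0.18 ± 0.13, -0.42 ± 0.14 and 0.73 ± 0.13 (adjusted p 0.0277). The other 2 were probe sets unnamed here, at 0.75 ± 0.11 and 1.12 ± 0.15 in mature leaves. Further genes named by rule did not pass: ACS, a plastid acetyl-CoA synthetase, was at 0.58 ± 0.08 in mature leaves against -0.04 ± 0.08 in primordia and 0.09 ± 0.09 in expanding leaves (adjusted p 0.106), and ChiC, a chitinase, at 0.61 ± 0.16 in mature and -0.79 ± 0.19 in expanding leaves (adjusted p 0.106). TMT1, a vacuolar monosaccharide transporter, was at -0.53 ± 0.08 in mature leaves, AT4G24790 at -1.31 ± 0.20, AT3G27400 at 1.37 ± 0.21 and AT2G38870 at 0.69 ± 0.20 (all with an adjusted p of 0.170 for the difference). The count of 4 was 0 without expanding ambient replicate 2, 2 without primordia ambient replicate 3 or 4, primordia elevated replicate 3 or 4, or mature ambient replicate 1 or 2, and 8, 12 and 10 without mature elevated replicate 1, elevated replicate 2 and ambient replicate 4. Without mature elevated replicates 3 and 4 together, chosen after seeing the data, it was 9.

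Between pairs of stages, limma called 1 probe set for mature against primordia, 4 for mature against expanding, and 0 for expanding leaves against primordia, with 1579, 1275 and 1486 at an unadjusted p under 0.05. The TCA cycle list responded more positively in mature leaves than in expanding leaves, with 16 of 16 differences positive (median 0.18, camera adjusted p 0.00793), and than in primordia, with 12 of 16 positive (median 0.16, adjusted p 0.0259). The 64 respiration genes had 54 positive differences against expanding leaves (adjusted p 0.000920) and 41 against primordia (adjusted p 0.0303). With an estimated correlation these were adjusted p = 0.419 for the TCA cycle in both pairs and adjusted p = 0.419 and adjusted p = 0.605 for respiration genes. Both pairs share the mature arrays, so they are not independent, and no single member passed. Fitted on the stages apart, the counts for mature leaves against primordia and against expanding leaves were 0 and 1, and array weights gave 31 for expanding leaves against primordia. Leaving out single arrays gave 0 to 23, 2 to 13 and 0 to 1 for the 3 pairs, with 23 without mature elevated replicate 2 and 13 without mature ambient replicate 4.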

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

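Tests chosen after the results were seen were those of the spread between arrays, of the shares of shared direction, of the developmental correlation, and the fits without elevated-CO2 mature replicates 3 and 4 together.

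AT3G22060 in ambient-CO2 mature replicate 1 lay at -2.49, away from the other 3 arrays of its group (-1.99 to -1.91). It was the only such array in 70 groups of 4 examined, of which chance would pick about 1 in 20. The CO2 effect differed between stages for AT1G77550 (adjusted p 0.0103 over the 3 stages and 0.00389 for mature against expanding leaves), AT4G36640 (0.0277 and 0.0270) and a probe set unnamed here (0.0103 and 0.00389). ChiC differed between mature and expanding leaves (0.0433), and another unnamed probe set over the 3 stages (0.0217) and between mature leaves and primordia (0.0149). Among lists, the TCA cycle differed between mature leaves and primordia (0.0259) and between mature and expanding leaves (0.00793), respiration genes likewise (0.0303 and 0.000920), and electron transport between mature and expanding leaves (0.0259). None of these held with an estimated correlation, with adjusted p = 0.419 for the TCA cycle in both pairs, adjusted p = 0.605 and adjusted p = 0.419 for respiration genes, and adjusted p = 0.601 for electron transport.

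Other splits of the same arrays bear on each count. For mature leaves, 2 of 35 splits called at least as many probe sets as the real 488. The other, at 707, exchanges ambient replicate 4 with elevated replicate 2, so chance is not excluded. A structure among these arrays apart from CO2 is possible and was not tested. The count was 849 without ambient replicate 4 and 1051 without elevated replicate 2; an exchange of these 2 labels is possible and was not tested, and the deposited labels were kept. For primordia it was 6 of 35 (real 1, highest other 4), which does not exclude chance, and expanding leaves have too few splits for a share under 0.05 (10 of 10 at or above the real 0, highest other 1). Over the 3 stages it was 2 of 100 draws (real 4, highest other 20), a share under 0.05. It was not adjusted for the other counts tested this way, and the count was 0 without expanding ambient replicate 2. It therefore speaks only weakly against chance. Mature against primordia and mature against expanding leaves gave 12 of 100 (real 1, highest other 265) and 8 of 100 (real 4, highest other 411), so chance is not excluded there. For expanding leaves against primordia the real count of 0 fixed the outcome at 100 of 100 (highest other 2), which says nothing about chance. Draws with 265 or 411 calls again leave a structure among the arrays possible. For the stages at ambient CO2 no other split called as many (1 of 35 splits each, 8292 against a highest other of 6737, and 5541 against 4542). Those highest others kept all expanding arrays together, so they nearly mirror the real labels. These shares speak against chance, but they are the smallest possible and were not adjusted for the other counts. For the TCA cycle list in mature leaves no other split went as far (1 of 35, mean t 1.81 above all probe sets, highest other 1.23). The same held for respiration genes there (1 of 35, 0.927 against 0.718), of which the TCA cycle genes are a part. A share of 1 of 35 is the smallest possible here, and both lists had already passed camera in these arrays. That choice was not adjusted for, so chance is not excluded for them. With an estimated correlation neither passed camera (adjusted p = 0.230 and adjusted p = 0.730).

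Mature leaves had more called probe sets than the other stages in the joint fit without weights or covariates. The ranking depended on the fit: with stages fitted apart 0 were called at each stage. With array weights expanding leaves had more calls than mature leaves, and with the 3-prime minus 5-prime covariate 279 against 239. The developmental position covariate, also chosen after seeing the data, went the other way, with 634 in mature and 0 in expanding leaves. The spread shared in the joint fit (median residual SD 0.173) lay below that of mature leaves (0.179), and its part in the ranking was not tested. The spread elsewhere was not larger, since the median residual SD of the other stages was at most 0.884 times that of mature leaves. The joint fit uses 1 spread per probe set for all stages, so this ratio cannot decide the ranking there. Fewer expanding arrays are argued against in part by the 16 subsets of 3 against 3 mature arrays, which called 253 at the median (16 to 1525). Subsets without elevated replicate 3 or 4 that kept ambient replicate 4 called only 16 to 38, so that median depends on these arrays. Replicates 3 and 4 of the elevated group stay open: without them 30 probe sets were called, while the median size of the 488 changes was 0.41 (median SE 0.14) against 0.54 (median SE 0.13) with all arrays, a loss partly built in because the 488 were picked with all arrays. These 2 arrays also had the lowest 3-prime minus 5-prime signal of control transcripts among mature arrays (1.12 and 1.01, against 1.19 to 1.25 in the others). With that signal as a covariate, chosen after seeing the data, 239 were called in mature leaves. An effect of the same direction in expanding leaves also stays open: 79.3% of the 488 had the same sign there, above the highest of the other 9 splits of those arrays (72.5%), whereas in primordia 56.4% did, below the highest of the other splits (61.7%). A stage difference in the number of genes that respond may therefore be smaller than the counts, and chamber and CO2 cannot be told apart.

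Plastid-encoded photosynthesis genes lay lower at elevated CO2 in mature leaves: 41 of 46 had negative changes and none was called, over all probe sets or over the list alone (median -0.19, camera adjusted p 0.0126, and adjusted p = 0.899 with an estimated correlation). Carry-over of RNA without poly(A) tails may account for part of it: within groups, the list mean followed the 25S ribosomal RNA signal over the 22 arrays (r = 0.716, permutation p 0.00016, adjusted over 3 relations 0.00048; rho = 0.678, permutation p 0.00074, adjusted 0.00222; r = 0.622 without the 2 arrays farthest out). Elevated replicates 3 and 4 carried it, since the median change without both was -0.013, but of these 2 arrays replicate 3 alone had a low 25S signal as well (3.65, list mean 2.69): replicate 4 lay at 4.37, near the ambient mean of 4.41, with a list mean of 3.01, against 3.03 in ambient replicate 4. The permutations of the 25S relation shuffled within-group deviations over all 22 arrays and not within groups, so their p-values tend to be too small. Of the 35 splits, 11 gave a mean t as far from 0 (real -0.889, highest other 1.49), so chance is not excluded. Replicate 4 lay at the lower edge of the ambient arrays (3.03 to 3.64), so it is not shown to be lowered. A CO2 effect on plastid transcripts stays open, for which camera's preset and estimated correlations gave opposite calls.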

How the results depend on the processing

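The fits without elevated-CO2 mature replicates 3 and 4 together and with covariates were chosen after the results were seen; the others were fixed before. No called change of a named gene turned its sign in any setting, while values of named genes that were not called changed sign 55 times in primordia, 47 in expanding leaves, 27 in mature leaves and 2 between stages. All 25 named genes called in mature leaves lost the call in at least 1 setting, and MT1C lost it in 2; of 162 called between stages, 144 kept it throughout. With stages fitted apart, limma called 0 probe sets in primordia, 0 in mature leaves (2087 at an unadjusted p under 0.05), 0 for mature against primordia and 1 for mature against expanding leaves; that fit has fewer arrays for its spread. Quantile normalization of all arrays gave 12 in expanding leaves, 7 for mature against expanding leaves and 2 lists between stages. It also moved the balance of directions between stages. Expanding leaves had 3947 higher and 4361 lower than primordia, against 4389 and 3903 in the main fit. Mature leaves had 2763 higher and 2821 lower than expanding leaves, against 2464 and 3077. Without the dimmest 30%, 2 were called in expanding leaves and 1 for expanding against primordia. Without the dimmest 50%, with fewer probe sets tested, counts were 2 over the 3 stages, 2 for mature against primordia, 1 for mature against expanding leaves, and 4649 and 3391 between stages. Array weights gave 2 in primordia, 387 in expanding leaves (154 higher), 261 in mature leaves, 8 for mature against expanding and 31 for expanding against primordia. At an adjusted p under 0.10, counts were 21 in expanding leaves, 1100 in mature leaves and 8 for mature against expanding leaves; with at least 1.5-fold, 192 in mature leaves and 5163 and 2655 between stages.

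With an estimated correlation, 0 lists passed under CO2, 0 between stages and 0 for the differences, against 2, 1 and 5 with the preset, and respiration genes in mature leaves had an adjusted p of 0.730. With fry, directional, that p was 0.117, 2 lists passed under CO2 (glycolysis lower in expanding and the TCA cycle higher in mature leaves), 8 between stages and 0 for the differences. With fry, mixed, 4 passed under CO2 (both of these, and electron transport and respiration genes in mature leaves), 12 between stages and 0 for the differences. With the 3-prime minus 5-prime signal as a covariate, 279 were called in expanding and 239 in mature leaves. With developmental position as a covariate, 634 were called in mature leaves and 0 in expanding leaves (1146 at an unadjusted p under 0.05 in expanding leaves). Position is computed from the same arrays and takes up part of the CO2 contrast. Without elevated replicates 3 and 4, 30 were called in mature leaves (19 of them among the 488), 9 over the 3 stages, 7 for mature against primordia and 23 for mature against expanding leaves. Except where the construction of an alternative is named, the cause was not tested.

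With the replicate number as a block, 0 were called in primordia, 277 in mature leaves, 0 over the 3 stages and 0 for mature against primordia. The labels do not say what a replicate number shares. Correlations between the deviations of same-numbered arrays from their group means ran from -0.248 to 0.26. For differently numbered arrays they ran from -0.499 to 0.513. In groups this small these values cannot decide whether the numbers pair the samples, so pairing stays open.

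Leaving out each array in turn, counts ran from 1 to 8 in primordia, 0 to 81 in expanding and 60 to 1051 in mature leaves. They ran from 0 to 12 over the 3 stages, 0 to 23 for mature against primordia, 2 to 13 for mature against expanding, 0 to 1 for expanding against primordia, and 7623 to 8122 and 4641 to 5661 between stages. Over the 3 stages it was 0 without expanding ambient 2, 2 without primordia ambient 3 or 4, primordia elevated 3 or 4, or mature ambient 1 or 2, and 8, 12 and 10 without mature elevated 1, elevated 2 and ambient 4. Lists passing ran from 1 to 3 under CO2, 1 to 2 between stages and 3 to 7 for the differences. The adjusted p of respiration genes ran from 0.000824 to 0.0595 in mature, 0.201 to 0.881 in expanding leaves and 0.0678 to 0.95 in primordia. Centring on the median and a logarithm with an offset were not run.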

Other observations

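The tests of the developmental correlation and of RNA quality against the position over all probe sets below were chosen after the results were seen. Among the additional lists, those of autophagy and of tetrapyrrole synthesis passed camera in expanding leaves with the preset correlation only. In expanding leaves, all 10 ATG8 and ATG3 genes had positive changes (median 0.27, camera adjusted p 0.000702, and adjusted p = 0.691 with an estimated correlation) and none was called, over all probe sets or over the list alone, with ATG8F, which tags autophagosome membranes, at 0.27 ± 0.12. In primordia all 10 were negative (median -0.11, camera adjusted p 0.00199, and adjusted p = 0.691 with an estimated correlation), with ATG8B at -0.63 ± 0.18 the only member past the threshold when adjusted over the list alone and 0 over all probe sets, and the difference between these stages had an adjusted p of 6.28e-06, and adjusted p = 0.372 with an estimated correlation. Tetrapyrrole synthesis genes were negative in 9 of 10 cases in expanding leaves (median -0.22, camera adjusted p 0.0131, and adjusted p = 0.814 with an estimated correlation) and in 9 of 10 in mature leaves (median -0.19, camera adjusted p 0.0257, and adjusted p = 0.852 with an estimated correlation), where PORB, a protochlorophyllide reductase, fell by 0.43 ± 0.11 (1 lower member in mature leaves over all probe sets and adjusted over the list alone, 0 in expanding leaves). All 8 cold and dehydration genes were negative in primordia (median -0.24, camera adjusted p 0.00199, and adjusted p = 0.351 with an estimated correlation), with 1 lower when adjusted over the list alone, XERICO (-0.36 ± 0.09), and 0 over all probe sets. In mature leaves 2 of the 8 were higher (COR47 and LTI30) and 3 lower (COR15A, COR15B and XERICO) when adjusted over the list alone, and 0 over all probe sets (camera adjusted p 0.796).

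In mature leaves, EXPA16 (-0.70 ± 0.17), XTH32 (-0.55 ± 0.14) and EXPA8 (-0.89 ± 0.24) fell among 11 expansin and xyloglucan-modifying genes (camera adjusted p 0.0859), and the tubulins TUB5 (-0.37 ± 0.10) and TUB6 (-0.34 ± 0.09) fell among 7 (camera adjusted p 0.0501), so neither list passed as a whole. Adjusted over the list alone, 4 expansin and xyloglucan-modifying genes were lower, with EXPA15 (-0.51 ± 0.17) added, and 3 tubulins, with TUB7 (-0.36 ± 0.14) added. Without elevated replicates 3 and 4 together, chosen after seeing the data, XTH32 was at -0.32 and TUB5 at -0.20, while EXPA16 was at -0.68, EXPA8 at -0.73 and TUB6 at -0.25, and none of these 5 called genes passed. Plastid genes of transcription and translation had 19 of 20 negative changes (median -0.28, camera adjusted p 0.0125, and adjusted p = 0.852 with an estimated correlation), none called over all probe sets or over the list alone. The 25S ribosomal RNA signal of these arrays was 4.12 ± 0.33 (SD, n = 4) at elevated against 4.41 ± 0.12 (SD, n = 4) at ambient CO2 (exact two-sided permutation p 0.171), lowest in elevated replicate 3 at 3.65, and elevated replicates 3 and 4 stood apart from the other mature arrays. Between expanding and mature leaves at ambient CO2, 8 of 10 ATG8 and ATG3 genes rose (10 adjusted over the list alone, median 0.68, camera adjusted p 0.000254, and adjusted p = 0.352 with an estimated correlation). Of 10 tetrapyrrole genes, 8 fell (8 adjusted over the list alone, median -0.58, camera adjusted p 0.00590, and adjusted p = 0.568 with an estimated correlation).

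A hypothesis is that expanding leaves at elevated CO2 were further in development at harvest: on an axis from ambient primordia (0) to ambient mature leaves (1), they lay at 0.776 ± 0.035 (SD, n = 3) against 0.671 ± 0.044 (SD, n = 3), with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays can give. On the axis without probe sets at an unadjusted p under 0.05 for CO2 at any stage, a filter that shrinks a CO2 shift, they lay closer. The positions there were 0.760 ± 0.031 (SD, n = 3) against 0.697 ± 0.034 (SD, n = 3), with an exact two-sided permutation p of 0.2. Elevated replicate 1 (0.725) lay below ambient replicate 1 (0.734) there. The CO2 effect of expanding leaves correlated over probe sets, which are not independent, with the change from primordia to mature leaves, an axis built from other arrays (r = 0.516, against at most 0.487 in the other 9 splits, too few to exclude chance). RNA quality was neither supported nor excluded as a candidate cause: within groups these positions correlated with the 3-prime minus 5-prime signal of control transcripts at r = -0.448 over 22 arrays (permutation p 0.0367, adjusted over the 3 such relations computed 0.0550; rho = -0.435, permutation p 0.0440, adjusted 0.0660; r = -0.390 without the 2 arrays farthest out). With positions over only the probe sets at an unadjusted p of 0.05 or more for CO2 at every stage, a filter that by itself makes a CO2 shift smaller, r was -0.389 (permutation p 0.0737, adjusted 0.0737; rho = -0.400, permutation p 0.0666, adjusted 0.0666; r = -0.334 without the 2 arrays farthest out). That sign would go with a lower position at elevated CO2, where the signal was 1.53 ± 0.16 (SD, n = 3), a difference of 0.13 from ambient CO2 (exact two-sided permutation p 0.3), the opposite of the shift seen. Permutations for the correlations with this signal shuffled deviations over all 22 arrays and not within groups, so their p-values tend to be too small.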
